A study of Mus musculus with 6 samples.

How the data were processed

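RNA from crude mitochondria of mouse hearts was sequenced in 6 libraries, 3 from control mice and 3 from Polrmt knockout mice. The mice were C57BL/6N animals aged 3 to 4 weeks, per the labels. Each library is taken as 1 mouse. Per the labels' protocols, RNA was isolated with the miRNeasy kit, libraries were made with the Illumina TruSeq kit, and paired-end reads were produced on a MiSeq. Whether the kit marked strand is not given in the sources used here.

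Per the submitters' processing notes, the tools were HISAT 0.1.6 for alignment, featureCounts 1.3.5-p4, R 3.2.0 and edgeR 3.11.2, with the genome build GRCm38. The deposited files hold raw counts per gene as whole numbers, in which the overlapping pairs mt-Atp8/mt-Atp6 and mt-Nd4l/mt-Nd4 share 1 value each, so that the 37 mtDNA genes are given as 35 values. The strand setting, the treatment of reads with several alignments and the annotation release are not given in the sources used here. A second set of deposited files holds values that the authors normalised and rounded, treated here as a score because the normalised values stand in no fixed ratio to the raw counts. The method of that normalisation is not given in the sources used here. The authors' deposited table of the comparison gives, per the file headers, a log2 fold change, an average log2 CPM, a likelihood ratio score, a p-value and a false discovery rate for 6319 genes. These were the genes with at least 1 count in all 6 libraries, except 6 mtDNA tRNAs.

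The raw counts were analysed here from the deposited files. Gene symbols and positions were taken from the GENCODE M21 annotation of GRCm38, in which 37570 nuclear identifiers had a symbol and 1572 identifiers had none. Knockout was compared with control by edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3, robust fit, no covariate), with the TMM scaling computed over the 3363 genes that passed filterByExpr (minimum count 10, minimum total count 15). That filter used the total library sizes, most of which are mtDNA counts in the controls. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called higher or lower, and tests were 2-sided. TMM sets the bulk of tested transcripts, nearly all of them nuclear, to no change. Fold changes of mtDNA genes are therefore relative to the nuclear transcripts in the same preparation and not to the number of mitochondria or cells. CPM values use TMM-scaled library sizes. The SE given with a log2 fold change is the one implied by its quasi-likelihood F statistic.

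Gene lists were fixed before the data were examined and tested with camera (limma 3.58.1) at a preset correlation of 0.01, and again with an estimated correlation. The fry test was run beside it, whose p tests whether the members of a list move one way on balance without comparing the list with other genes. Lists with fewer than 3 tested members received counts only. The mtDNA genes were also fitted alone against the mtDNA total of each library, to compare mtDNA transcripts with each other. Light-strand promoter genes were compared with heavy-strand promoter genes by the log2 ratio of their counts per library. Single values per library were compared by an exact permutation test, which for 3 against 3 gives no p below 0.1. The relation of fold change to distance from the promoter was tested across genes with 100000 permutations.

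The genes named in the text followed a rule fixed before the data were examined. It took Polrmt, the tested mtDNA mRNAs and rRNAs, and the 4 tested mtDNA tRNAs with the smallest adjusted p. It also took the 10 nuclear genes with the largest change in each direction among called genes of at least median expression whose groups did not overlap, leaving out predicted genes and sex-linked genes. Up to 4 called members of each list were added, of which 1 is not reported here. Other members are named with their values, and those were chosen after their values were seen. A fold change against a group with no counts is given as a bound computed from 3 counts over the group. Where a group held 1 to 3 counts, the ratio is given with its 95% Poisson interval.

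Gene-assigned totals were 3019615, 3234729 and 2867067 in controls and 1062030, 1090816 and 1227997 in knockouts. Most of these counts come from mtDNA rRNAs and 5 nuclear loci, which leaves between 76949 and 164004 counts per library for the other nuclear genes. A nuclear gene at 3 counts lies between 1.16 and 2.55 CPM, so genes near or under this level give no precise fold change. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. Replicates of a group differed by more than sampling noise in a chi-square test over nuclear genes, with chi-square per degree of freedom between 1.30 and 6.26, so no library was a copy of another. Xist and the Y-linked genes showed control 2 and knockout 1 to be from female mice and the others from male mice.

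The procedure was tested on simulated data with the means and library sizes of the comparison of knockout with control. Among 3363 simulated genes, 100 nuclear genes were changed by 2-fold and 100 by 4-fold. The edgeR test recovered 42.0% of the genes changed 2-fold and 85.0% of those changed 4-fold, with 8 of 135 nuclear calls among unchanged genes. DESeq2 recovered 21.0% and 73.0%. With no nuclear gene changed, edgeR called 0 nuclear genes and camera 0 of 22 nuclear lists. These are simulated counts without the structure of real libraries.

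Alternatives fixed beforehand were no scaling, TMM over nuclear genes, DESeq2 1.42.0, no low-count filter, the genes of the authors' normalised files, edgeR's exact test, a replicate block, each library left out, stricter thresholds, and other definitions of the mtDNA ratios. Added after seeing the data were a filter on scaled library sizes, sex as a term, the authors' gene-specific factors as offsets, and the removal of the 5 nuclear loci. Transcripts with at least 80% identity to mtDNA were sought with BLAST 2.17.0. The genome sequence was not used here. One test of mtDNA carry-over was first run in a form that took a floor off the controls as well. It left mt-Nd6 with 0 control counts there, gave a meaningless log2 fold change of 11.82 for mt-Nd6, and was replaced, after that value was seen, by the form given among the other observations. The readings of the light-strand tRNA test and of the synthetase test were set to undecided after they were run, because too few counts or genes stood behind them.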

Results

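RNA of crude heart mitochondria was profiled by RNA sequencing in 3 control mice, with loxP-flanked Polrmt alleles and no cre, and in 3 mice in which cre under a muscle creatine kinase promoter removed exon 3 of Polrmt. Polrmt encodes the RNA polymerase of mitochondria, which transcribes mtDNA and makes the primers for its replication. The title of the series concerns the choice between those activities, and the comparison asks which transcripts differ when the polymerase is removed from heart muscle. Gene-assigned counts were between 2867067 and 3234729 in controls and between 1062030 and 1227997 in knockouts.

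Polrmt, the targeted gene (ENSMUSG00000020329, chromosome 10, 79736123 to 79746581, GRCm38), had 3, 2 and 1 counts in controls and 2, 5 and 1 counts in knockouts. The ratio of knockout to control, scaled by effective library size, was 0.850 with a 95% Poisson interval from 0.259 to 2.97. A gene-level count includes the exons that remain and does not resolve exon 3, so these counts check neither the deletion nor the labels.

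Transcripts of mtDNA made up 81.9% ± 2.10 (SD, n = 3) of counts in control libraries and 22.8% ± 2.65 (SD, n = 3) in knockout libraries. The share of control 1 was 83.5% (95% Clopper-Pearson interval 83.4 to 83.5) and that of knockout 3 was 25.8% (25.8 to 25.9). The mtDNA rRNAs made up 68.3% ± 2.24 of control counts (SD, n = 3) and fell by 47.3 points in knockouts, and the mtDNA mRNAs fell from 13.6% ± 0.177 to 1.78% ± 0.211 (SD, n = 3 each). All 3 knockouts lay below all 3 controls, and the exact permutation p was 0.1, the smallest that 3 against 3 allows. Among nuclear counts, 5 loci (Gm42418, Lars2, Gm23935, Gm15564 and Mir6236) held 82.2% ± 2.11 in controls and 83.4% ± 1.47 in knockouts (SD, n = 3 each), a difference smaller than the spread (exact permutation p = 0.4). Gm42418 lies on chromosome 17 (39846958 to 39848788), at a place known to carry a copy of the cytosolic rRNA precursor. With these loci left out, a choice made after seeing the data, the mtDNA share was 96.2% ± 0.808 in controls and 63.9% ± 2.01 in knockouts (SD, n = 3 each, exact permutation p = 0.1).

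**Figure D1:**
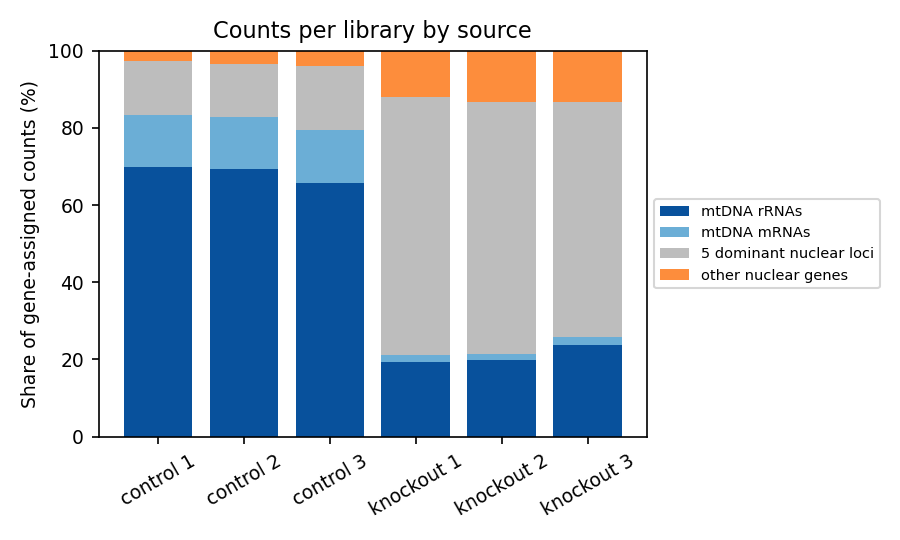
Share of gene-assigned counts (percent, stacked bars) from mtDNA rRNAs, mtDNA mRNAs, 5 dominant nuclear loci and other nuclear genes in each of the 6 libraries; mtDNA tRNAs are too few to see. The mtDNA share is 79.5% or more in the controls and 25.8% or less in the knockouts.

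Transcripts of mtDNA genes were lower in the knockouts relative to nuclear transcripts. All 17 tested of 35 mtDNA values fell (edgeR adjusted p under 0.05, also when adjusted over the list alone), and the other 18, all tRNAs, did not pass the low-count filter. With no low-count filter, 29 mtDNA values were tested and 20 were lower. The 10 mRNA values transcribed from the heavy-strand promoter, which encode subunits of complexes I, III, IV and V, fell between 30.1-fold and 41.7-fold. mt-Nd2 (position 3914 to 4951 of the mtDNA), a complex I subunit, fell from 21319 ± 4380 to 511 ± 68.3 CPM (SD, n = 3 each; log2 fold change -5.38 ± 0.22 SE, edgeR adjusted p = 6.28e-58). mt-Co1 (5328 to 6872), the catalytic subunit of cytochrome c oxidase, fell from 89719 ± 16244 to 2554 ± 115 CPM (log2 fold change -5.13 ± 0.23 SE), and mt-Cytb (14145 to 15288), the mtDNA-encoded subunit of complex III, had a log2 fold change of -5.11 ± 0.22 SE. The smallest fall among these mRNAs was that of mt-Co2 (7013 to 7696), at -4.91 ± 0.21 SE.

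The mtDNA rRNAs fell less than the heavy-strand mRNAs. mt-Rnr1 (70 to 1024), the small rRNA of the mitochondrial ribosome, had a log2 fold change of -4.12 ± 0.24 SE (17.4-fold lower), and mt-Rnr2 (1094 to 2675), the large rRNA, one of -3.69 ± 0.24 SE (12.9-fold lower). The log2 ratio of rRNA to mRNA counts was 2.32 ± 0.06 in controls and 3.56 ± 0.02 in knockouts (SD, n = 3 each, exact permutation p = 0.1). Among tRNAs, mt-Ti (3706 to 3774) had 482 counts over the controls and 9 over the knockouts, with a log2 fold change of -6.37 ± 0.61 SE. The others tested were mt-Tw at -5.28 ± 0.30, mt-Tm at -4.93 ± 0.34 and mt-Tv, which lies between the rRNA genes, at -3.78 ± 0.42 (log2, SE). Counts of tRNA genes were uneven, with 0 in every library for mt-Tg, mt-Ts2, mt-Tl2, mt-Tq, mt-Ta and mt-Ty. Gene counts do not tell mature tRNAs from longer transcripts that span them, so these values may not measure tRNA levels.

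mt-Nd6 (13552 to 14070), a complex I subunit and the mRNA transcribed from the light-strand promoter, had the smallest fall of the tested mtDNA genes. It fell from 835 ± 151 to 325 ± 66.6 CPM (SD, n = 3 each), 2.56-fold (log2 fold change -1.36 ± 0.15 SE, edgeR adjusted p = 1.09e-13), and this direction turned with no scaling beyond the library size, where it was 0.77 on the log2 scale. Its share of mtDNA mRNA counts, which needs no scaling, was 0.290% ± 0.00572 in controls and 3.69% ± 0.408 in knockouts (SD, n = 3 each). The log2 ratio of light-strand to heavy-strand promoter counts was -10.998 ± 0.04 in controls and -8.43 ± 0.18 in knockouts (SD, n = 3 each), a difference of 2.57 that was larger than the spread (exact permutation p = 0.1). Nearly all light-strand counts were those of mt-Nd6 (3600 in controls and 2262 in knockouts). This ratio thus largely restates the result of mt-Nd6 and is no separate evidence on the promoters. The 8 light-strand tRNAs together held 54 counts in controls and 10 in knockouts, which is a log2 fold change of -3.08 with a 95% Poisson interval from -4.22 to -2.09, and no knockout library had more than 5 of these counts. The 14 heavy-strand tRNAs together had a log2 fold change of -4.94 (95% Poisson interval -5.22 to -4.68).

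**Figure D2:**
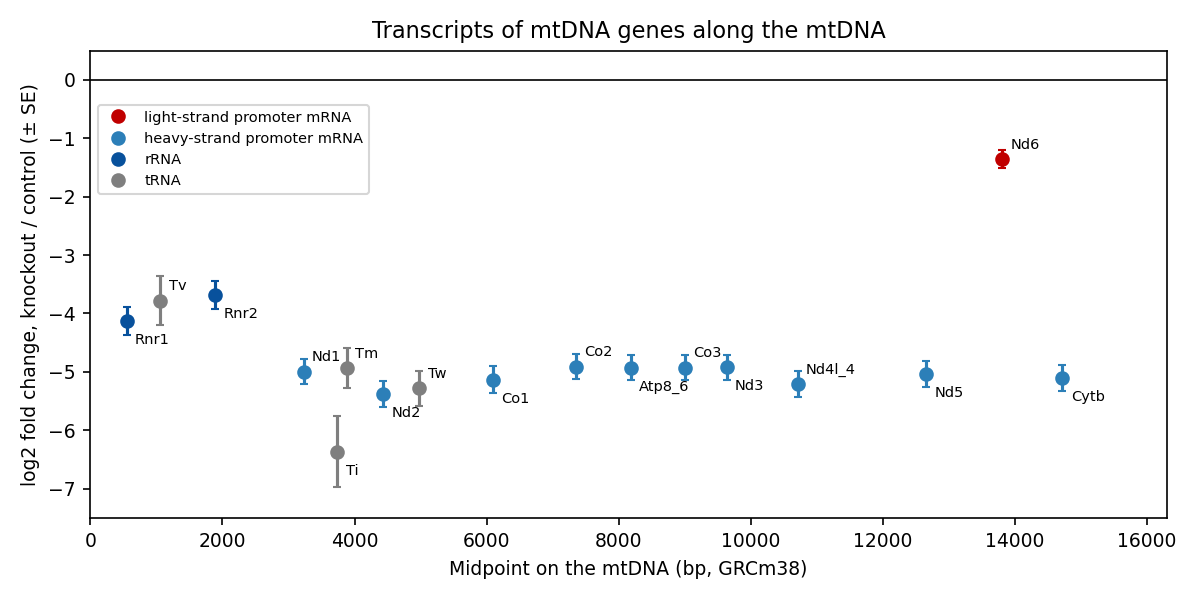
edgeR log2 fold change of knockout against control (± SE, n = 3 each) for the 17 tested mtDNA genes by position on the mtDNA (bp, GRCm38), with TMM scaling. mt-Nd6 lies at -1.36 (above 0 with no scaling, at 0.77), the rRNAs at -4.12 and -3.69, and the heavy-strand mRNAs between -5.38 and -4.91.

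Measured against the mtDNA total alone, 2 of the 17 tested mtDNA genes were higher in knockouts and 13 were lower (edgeR adjusted p under 0.05). mt-Nd6 was 6.01-fold higher (log2 fold change 2.59 ± 0.11 SE) and mt-Rnr2 1.21-fold higher (0.28 ± 0.01 SE). mt-Nd2 was 2.69-fold lower (log2 fold change -1.43 ± 0.06 SE) and mt-Ti 5.49-fold lower (-2.46 ± 0.73 SE), while mt-Tv (0.14 ± 0.59 SE) and mt-Tw (-1.40 ± 0.77 SE) did not pass the test. mt-Tw passed it with the replicate block, without control 1 (adjusted p = 0.00234) and without control 3 (6.23e-04). The call of mt-Tm was lost without control 2, knockout 1 or knockout 3 (highest adjusted p 0.200). Since mt-Rnr2 holds most of the total, sizes and directions depend on it: against the total without the rRNAs, 5 genes were higher and 2 lower. The log2 fold change of mt-Nd6 was then 3.67, that of mt-Rnr2 1.36 and that of mt-Nd2 -0.34, and mt-Ti no longer passed (adjusted p = 0.112). The call turned from lower to higher for mt-Rnr1 (-0.16 to 0.92), mt-Co2 (-0.96 to 0.13) and mt-Co3 (-0.97 to 0.12). Also called lower at first, mt-Nd1 (0.05), mt-Tm (0.11), mt-Atp8_6 (0.12), mt-Nd3 (0.13) and mt-Nd5 (0.007) then lay above 0 without passing the test. Across the 16 tested heavy-strand genes, the fold change showed no detected relation with distance from the promoter (Spearman rho -0.31, permutation p = 0.247, adjusted over both gene sets 0.493; Pearson r -0.38, permutation p = 0.149, adjusted 0.298). Over the 10 mRNA values rho was 0.02 (permutation p = 0.973, the same when adjusted) and Pearson r was 0.17 (permutation p = 0.646). Without the 2 genes farthest from the median distance, rho over the 16 genes was -0.27 and r was -0.43. The same step over the 10 mRNA values gave a rho of 0.17 and an r of 0.48, with the opposite sign. These relations are across genes, which are not independent replicates.

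Of the 9 nuclear copies of mtDNA in the list fixed for them, 3 are in the files and 1 was tested and was lower, also over the list alone. Gm13340, a pseudogene with 97.6% identity to mt-Co1, had a log2 fold change of -5.32 ± 0.30 SE (-5.94 without knockout 1), and such copies are uncertain because reads of mtDNA transcripts can align to them. Gm10222, a copy with 100% identity to mt-Nd4l that is not in the list and was named after its value was seen, had a log2 fold change of -4.20 ± 0.29 SE (edgeR adjusted p = 1.83e-27). Both count among the nuclear genes called lower. The listed copies held 111 ± 16.6 counts per control library and 6.00 ± 4.58 per knockout library (SD, n = 3 each).

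Outside mtDNA, 223 nuclear genes were higher and 211 lower in knockouts among 3346 tested (edgeR adjusted p under 0.05), with 407 and 418 at an unadjusted p under 0.05. Over all 3363 tested genes the groups did not overlap in 29.3%, where chance gives 10%. Genes called lower were so relative to the bulk of nuclear transcripts, as no scaling beyond the library size shifts the median log2 fold change by 2.08 and gives 3326 nuclear genes higher and 2 lower. Of all calls, mtDNA genes included, 49.4% were higher, against 99.5% with no scaling, 63.9% with the authors' gene-specific factors and 62.6% without the low-count filter. The median shift was 0.11 with the authors' factors, 0.11 on the authors' genes and 0.13 without the filter. DESeq2 called 89 nuclear genes higher and 56 lower. The edgeR test called 117 nuclear genes lower without knockout 1, 135 without control 2, 97 without the low-count filter, 134 on the authors' genes and 119 with the authors' factors.

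Among nuclear genes of at least median expression, the largest rise was that of Nmrk2 (chromosome 10, 81198170 to 81202051), a nicotinamide riboside kinase of muscle. It had 1 count over the controls, in control 1, and 318 over the knockouts, a ratio of 203 with a 95% Poisson interval from 36.1 to 8032. Tenm4, a teneurin of the cell surface, had 2 counts, both in control 2, and 133 counts, a ratio of 42.4 (11.5 to 354). Acta1, the skeletal muscle actin, rose from 7.02 ± 6.00 to 98.1 ± 10.6 CPM (SD, n = 3 each; log2 fold change 3.92 ± 0.25 SE, edgeR adjusted p = 6.74e-17). Nppb, which encodes brain natriuretic peptide, rose 9.19-fold, Ankrd1, a stress-responsive protein of heart muscle, 6.76-fold, and Cyb5r1, a cytochrome b5 reductase, 7.56-fold. Sars rose 6.72-fold, Gars 6.68-fold and Aars 6.20-fold, which are aminoacyl-tRNA synthetases, and Acot2, a mitochondrial acyl-CoA thioesterase, 5.61-fold. Some of these sizes rest on 1 control with few counts: the log2 fold change of Acta1 was 4.70 without control 1, and that of Nppb, 3.1996 with all libraries, was 4.27 without control 1 and 2.57 without control 2. Sars went from 2.75 to 3.34 without control 3, Gars from 2.74 to 3.79 without control 3, and Aars from 2.63 to 3.33 without control 2.

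The largest falls were smaller in size than the rises, and all of those named here had fitted changes above 0 with no scaling beyond the library size. The low-count filter used total library sizes, which were larger in controls. A gene expressed in controls alone thus needed more counts to be tested than one expressed in knockouts alone. Whether this made the falls smaller was not tested. Trabd2b fell 3.94-fold (log2 fold change -1.98 ± 0.33 SE, edgeR adjusted p = 5.39e-07), Slc44a2, a choline transporter-like protein, 3.33-fold, and Cmya5, a protein of striated muscle, 3.27-fold from 89.6 ± 9.38 to 27.2 ± 5.87 CPM (SD, n = 3 each). Pcsk6, a proprotein convertase, fell 3.26-fold, Ppm1k, the phosphatase that activates branched-chain amino acid breakdown, had a log2 fold change of -1.64 ± 0.33 SE, and Pink1, a kinase of mitochondrial quality control, fell 2.96-fold. Dpt, Csf1r, Tcap and Chd6, a chromatin remodeller, fell between 2.63-fold and 2.80-fold.

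Genes of the integrated stress response and one-carbon metabolism rose together. Of 22 tested members, 17 were higher, 1 was lower and 4 did not pass, and 19 were higher and 1 lower when adjusted over the list alone. DESeq2 called 11 of the 22 higher and 0 lower. Camera gave an adjusted p of 4.71e-19, and the adjusted p was 0.0357 with an estimated correlation. No counts were found in any control for Asns, the asparagine synthetase, which was at least 16.8-fold higher, and for Mthfd2, a mitochondrial enzyme of one-carbon metabolism, which was at least 14.2-fold higher. Trib3, a pseudokinase of the stress response, was at least 7.22-fold and Gdf15, a secreted stress signal, at least 7.01-fold higher (against 3 counts over the group). Atf4, the transcription factor of this response, had a log2 fold change of 1.93 ± 0.43 SE and Atf5 one of 1.47 ± 0.34 SE. Vldlr, a lipoprotein receptor, was the member that fell (-0.56 ± 0.20 SE), its direction turns with no scaling, and its call held only with all libraries or without knockout 3 (highest adjusted p 0.188).

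Mitochondrial chaperones and proteases rose in 6 of 16 tested members, with 0 lower and 10 not past the test, and 8 were higher when adjusted over the list alone. Lonp1, the protease of the matrix, rose from 9.38 ± 1.77 to 45.5 ± 3.25 CPM (SD, n = 3 each; 4.73-fold). Hspe1 rose 7.04-fold, Hspd1 2.42-fold and Hspa9 2.15-fold, the first a co-chaperone of the second, and Hspe1, with 5 control counts, went from 2.82 to 4.32 on the log2 scale without control 2. Hspb7 (0.75 ± 0.15 SE, log2), a small heat shock protein of muscle that is not confined to mitochondria, and Clpb (1.36 ± 0.45 SE) were the others past the test, named after their values were seen, and the call of Clpb was lost without control 1, control 2, knockout 1 or knockout 3 (highest adjusted p 0.224). The camera adjusted p was 1.55e-07, and the call was lost with an estimated correlation (adjusted p = 0.0784).

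Cardiac hypertrophy genes were higher in 8 of 13 tested members, lower in 1 and not past the test in 4, and adjusted over the list alone 9 were higher and 1 lower. Xirp2, an actin-binding protein of the muscle, rose 4.12-fold, from 48.6 ± 10.5 to 197.9 ± 11.1 CPM (SD, n = 3 each), and Nppa, which encodes atrial natriuretic peptide, 2.92-fold. Fhl2, a LIM protein of the heart, fell 2.59-fold, a direction that turns with no scaling. The camera adjusted p was 2.82e-12, and it was 0.0784 with an estimated correlation. Beside these genes, fibroblast markers had a median log2 fold change of -0.44, which lay above 0 with no scaling.

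Transcripts of cytosolic ribosomal proteins were higher in 7 of 38 tested members, with 0 lower and 31 not past the test, and 12 were higher when adjusted over the list alone. The fitted change was above 0 in 37 of the 38, with a median of 0.73 on the log2 scale. Rplp1 rose 2.14-fold, Rpl4 2.02-fold and Rplp0 1.72-fold. DESeq2 called 2 of the 38, and Rplp0 was not among its calls (adjusted p = 0.0648). Camera gave an adjusted p of 2.05e-07, and 0.0357 with an estimated correlation.

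Genes of the sarcomere and of calcium handling moved both ways, with 3 higher, 10 lower and 11 not past the test among 24, and the same numbers when adjusted over the list alone. DESeq2 called 1 higher and 8 lower. Those that fell, relative to other nuclear transcripts, had fitted changes above 0 with no scaling. Ryr2, the calcium release channel of the sarcoplasmic reticulum, fell 2.46-fold (log2 fold change -1.30 ± 0.14 SE), and Atp2a2, its calcium pump, 2.01-fold, from 1477 ± 69.0 to 734 ± 96.1 CPM (SD, n = 3 each). Tcap, the titin cap of the sarcomere, fell 2.69-fold and Tpm1, a tropomyosin, 1.92-fold. Mybpc3 (0.54 ± 0.14 SE), Ldb3 (0.51 ± 0.15 SE) and Des (0.43 ± 0.15 SE, log2) rose, and the call of Des was lost without control 1, control 2, control 3, knockout 2 or knockout 3 (highest adjusted p 0.178), and that of Ldb3 without knockout 2 (0.0720). The camera adjusted p was 3.75e-05 for a fall, and 0.166 with an estimated correlation.

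**Figure D3:**
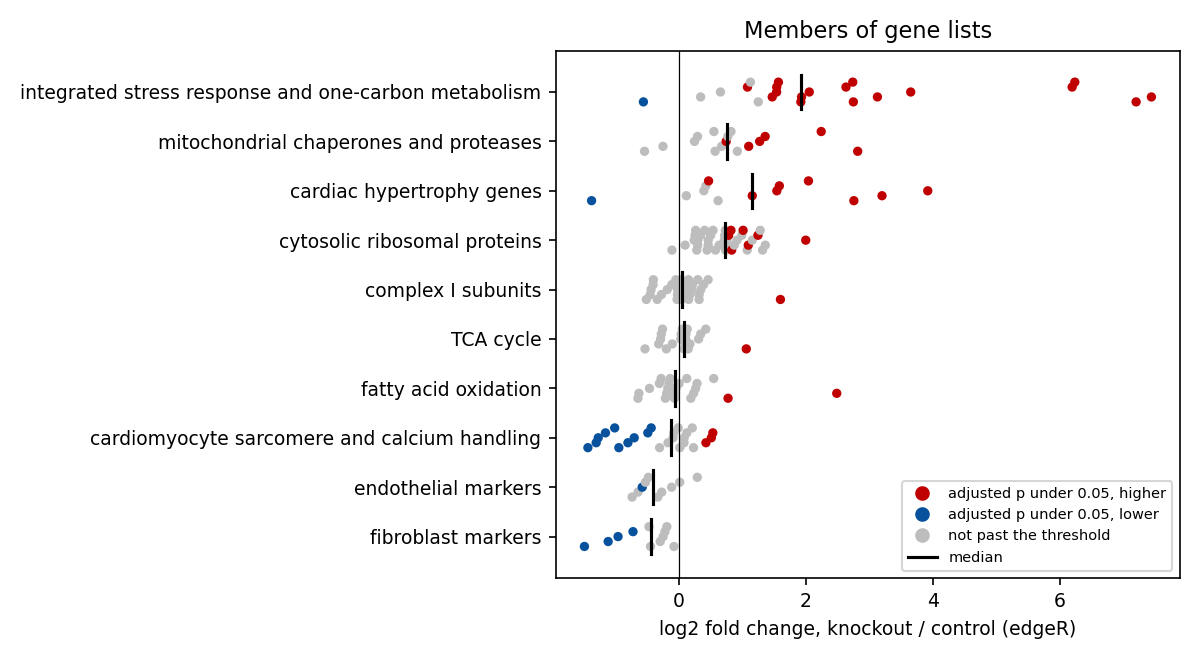
edgeR log2 fold change (knockout against control, n = 3 each, TMM scaling) of tested members of 10 gene lists, with each list's median as a bar and members past an adjusted p of 0.05 in colour. The stress response list has a median of 1.93 and the complex I list one of 0.04 (with no scaling beyond the library size the median of every list shown lies above 0). The 4 points beyond 6 are genes with 0 control counts, whose fitted values are not bounds.

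Nuclear genes of the respiratory chain and of fuel use had few calls. Among complex I subunits 1 of 31 tested was higher (Ndufa2, 3.03-fold), and among complex IV subunits 1 of 13 was lower (Cox7a1, 2.11-fold, turning with no scaling and not called by DESeq2, adjusted p = 0.0659). The 4 complex II and 9 complex III subunits had no call at an adjusted p under 0.05. Atp5f1 of ATP synthase rose 1.44-fold among 14, Pdhb of pyruvate dehydrogenase 2.09-fold among 21 genes of the TCA cycle, and Fabp3, a fatty acid binding protein, 1.71-fold among 22 genes of fatty acid oxidation, where Acot2 was the other call. Coq5 of coenzyme Q synthesis rose 2.19-fold among 5, and Trnt1, which adds the end of tRNAs, 3.55-fold among 8 factors of mitochondrial RNA processing. Mitoribosomal proteins (13 tested, median log2 fold change 0.20), mitochondrial import (7 tested, 0.56) and the endoplasmic reticulum (13 tested, -0.04) had no call. Adjusted over the list alone, these counts changed in coenzyme Q synthesis, where Coq8a (-0.44 ± 0.18 SE) also passed. With TMM scaling none of these lists passed camera, while fry, which does not compare a list with other genes, gave an adjusted p of 0.0120 for a rise of mitoribosomal proteins and 0.0322 for a rise of mitochondrial import. With no scaling every tested member of the complex I list (31 of 31) and of the TCA cycle (21 of 21) was called higher, and camera then passed ATP synthase (adjusted p = 0.00431), the TCA cycle (5.27e-07) and fatty acid oxidation (0.00143). The fatty acid oxidation list had a median of -0.059 and a mean of 0.07 with a camera direction of up, and the coenzyme Q list a median of 0.018 and a mean of 0.12 with a direction of down. Calls were lost with a library left out for Trnt1 (control 2, control 3 or knockout 3, highest adjusted p 0.143) and Ndufa2 (control 2, control 3 or knockout 2, 0.0554). The same held for Atp5f1 (control 2 or knockout 3, 0.249) and Coq5 (control 2, control 3, knockout 2 or knockout 3, 0.188). DESeq2 called none of these 4 genes (lowest adjusted p 0.232, for Ndufa2).

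Markers of fibroblasts, endothelium, smooth muscle and immune cells had medians below 0 relative to other nuclear transcripts, and above 0 with no scaling. The RNA is that of crude mitochondria, and whether these markers follow the amounts of these cells in the heart was not tested. Fibroblast markers had 4 lower of 11 tested and 0 higher (5 lower when adjusted over the list alone), among them Gsn, Mmp2 and Pdgfra, with a camera adjusted p of 3.66e-05 (adjusted p = 0.161 with an estimated correlation). Endothelial markers had 1 lower of 10 (Kdr, 1.49-fold; 2 over the list alone), at a camera adjusted p of 0.0413 (0.173 as the adjusted p with an estimated correlation). That camera call was lost when control 1 (adjusted p = 0.0951), control 3 (0.0527) or knockout 1 (0.0876) was left out. Smooth muscle and pericyte markers had 3 lower and 1 higher of 7, also over the list alone, with Des, also a muscle gene, higher and Acta2 2.14-fold, Abcc9 1.80-fold and Pdgfrb 1.78-fold lower, at a camera adjusted p of 0.0392 (0.554 as the adjusted p with an estimated correlation). It was lost without control 1 (0.0546), control 2 (0.106) or knockout 1 (0.302), and fry gave an adjusted p of 0.183 for this list. For a fall of fibroblast markers and of endothelial markers, fry gave an adjusted p of 0.0120 each. Of 14 immune markers 2 could be tested, Csf1r and Lyz2, and both were lower, by 2.79-fold and 2.23-fold. Calls were lost with a library left out for Pdgfra (any but knockout 3, highest adjusted p 0.117) and Kdr (control 1, control 2, knockout 1 or knockout 2, 0.227). The same held for Acta2 (control 2, 0.0777) and Lyz2 (control 1 or knockout 1, 0.226). DESeq2 called none of Pdgfra, Kdr, Pdgfrb, Des and Lyz2 (lowest adjusted p 0.0789, for Pdgfrb). Erythroid markers (5 tested, median -0.11) and Plin4, the adipocyte marker tested (0.40 ± 0.23 SE), had no call. Of skeletal muscle markers Acta1 rose and Ckm did not pass (0.02 ± 0.14 SE), and Myh1, Myh2 and Myh4 had 0 counts in every library.

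Among other RNAs, Rn7sk, which regulates transcription elongation, fell 1.37-fold, and Rn7s2, an RNA of the signal recognition particle, 1.49-fold, both turning with no scaling. The call of Rn7sk was lost without control 2, control 3 or knockout 2 (highest adjusted p 0.149) and that of Rn7s2 without control 1, control 2, knockout 2 or knockout 3 (0.211), and DESeq2 called neither (adjusted p = 0.226 and 0.302). Rmrp (0.44 ± 0.16 SE), Rpph1 (0.14 ± 0.15 SE) and Rn7s1 (-0.10 ± 0.22 SE) did not pass. Over the list alone Rmrp was also higher. The nuclear RNAs Neat1 (0.63 ± 0.23 SE) and Malat1 (-0.10 ± 0.14 SE) did not pass, and Neat1 did when adjusted over the list alone. Of 25 factors of mtDNA replication and transcription 1 could be tested, Polg, the mtDNA polymerase, at 0.24 ± 0.41 SE.

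The authors' deposited table lists 195 genes higher and 141 lower at a false discovery rate under 0.05. Of 3275 genes in both, 287 were called in both with the same sign and 0 with opposite signs, 121 were called here alone and 16 by the authors alone. A further 43 genes called here are not in the authors' table. The authors' deposited table ranks mt-Nd3, a complex I subunit, first by p, with a log2 fold change of -7.63, where the raw counts gave -4.92 ± 0.22 SE here. The ratio of the deposited normalised value to the raw count of mt-Nd3 was 6.42, 7 and 7 in controls and between 0.490 and 0.763 in knockouts, where the other mtDNA mRNAs had ratios near those of mt-Nd1, 1.09 on average in controls and 0.735 in knockouts.

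**Figure D4:**
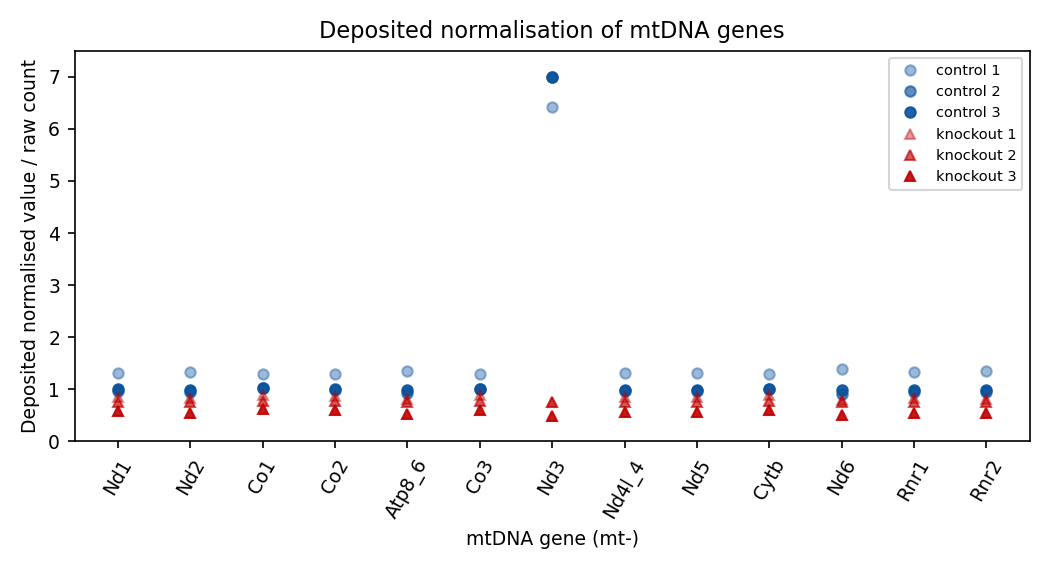
Ratio of the deposited normalised value to the raw count for each mtDNA mRNA and rRNA in the 6 libraries (circles, controls; triangles, knockouts). mt-Nd3 has ratios of 6.42, 7 and 7 in the controls, apart from the other genes.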

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

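The fall of heavy-strand mtDNA transcripts and the rise of the stress response list kept their direction and side of the threshold in every alternative run. The filter on scaled library sizes, sex as a term, the authors' factors and the removal of 5 nuclear loci were chosen after seeing the data. At these depths and with 3 mice per group, the self-test recovered 42.0% of genes changed 2-fold in the comparison of knockout with control (3363 genes); depth was not varied on its own. Depth limits weakly expressed genes, since 3 counts are 1.16 to 2.55 CPM. Against 223 genes higher in knockout and 228 genes lower in knockout, mtDNA genes included here and in the counts that follow, DESeq2 gave 89 and 73, an adjusted p under 0.01 gave 140 and 130, and a test against 1.5-fold gave 91 and 53. Genes lower were 117 with no low-count filter, 147 on the genes of the authors' normalised files and 132 with the authors' gene-specific factors; the cause was not tested. Leaving out each library gave 152 to 204 genes higher and 134 to 187 lower, both lowest without knockout 1, with fewer samples in each fit. The filter on scaled library sizes left 2313 genes to test, with 210 higher and 180 lower, and kept 160 of the 223 and 167 of the 228 calls. No call turned to the opposite direction in these settings. With no scaling beyond the library size, however, 193 of the 228 genes called lower were called higher. The calls of 15 named genes were lost in at least 1 alternative, 14 under DESeq2. Turning with no scaling was not counted as a loss.

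No label says that the replicate numbers pair the mice. Same-numbered samples had deviation correlations of -0.020, 0.018 and 0.022, which at these depths cannot show whether the mice were paired. With the replicate block, 210 genes were higher and 218 lower, 17 mtDNA genes were lower, and the light-strand against heavy-strand ratio kept its difference of 2.57. The block changed no call of a gene list.

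The share of counts from mtDNA genes changed by -59.2 points, by -40.9 for mtDNA mRNAs as a share of the counts outside mtDNA rRNAs and tRNAs, and by -32.3 outside the dominant nuclear loci. It changed by -60.7 to -58.3 with a library left out. The difference of light-strand against heavy-strand promoter transcripts was 3.72 for mRNAs only, 3.70 without the rRNAs and 1.76 for tRNAs only, and 2.50 to 2.67 with a library left out. The composition among mtDNA genes had 5 higher and 2 lower with the library size without the rRNAs, which by construction takes mt-Rnr2 out of the total; a library left out gave 2 higher and 12 to 14 lower. Promoter distance over tRNAs alone was not run, with 4 heavy-strand and 0 light-strand tRNAs tested.

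With an estimated correlation, gene lists called were 2 higher and 3 lower, and adjusted p rose to 0.0784 for mitochondrial chaperones and proteases and for cardiac hypertrophy genes, 0.166 for cardiomyocyte sarcomere and calcium handling, 0.161 for fibroblast markers, 0.173 for endothelial markers and 0.554 for smooth muscle and pericyte markers. Fry, which does not compare a list with other genes, gave an adjusted p of 0.00711 for mitochondrial chaperones and proteases. It gave 0.0120 each for cardiac hypertrophy genes and for cardiomyocyte sarcomere and calcium handling. With a library left out, 4 lists were higher and 5 to 7 lower by camera, with adjusted p from 0.0250 to 0.0951 for endothelial markers and from 0.00957 to 0.302 for smooth muscle and pericyte markers.

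No scaling beyond the library size gave 3327 genes higher and 18 lower, since mtDNA counts fill the control totals. It also gave 9 gene lists higher and 3 lower, and why the list calls changed was not tested. ATP synthase subunits (adjusted p = 0.00431), TCA cycle (5.27e-07) and fatty acid oxidation (0.00143) then passed, while endothelial markers did not (0.754). Lists that turned were cardiomyocyte sarcomere and calcium handling (2.06e-04), small and structured noncoding RNAs (0.0253), fibroblast markers (0.665) and smooth muscle and pericyte markers (0.547, edgeR with camera). The named genes that turned, all to a log2 fold change above 0, were mt-Nd6 0.77, Trabd2b 0.11, Slc44a2 0.35, Cmya5 0.38, Pcsk6 0.39, Ppm1k 0.45, Pink1 0.54, Dpt 0.61, Csf1r 0.60, Tcap 0.67, Chd6 0.69, Cox7a1 1.02, Fhl2 0.71, Ryr2 0.79, Tpm1 1.14, Atp2a2 1.104, Rn7sk 1.62, Rn7s2 1.54, Gsn 1.16, Mmp2 0.99, Pdgfra 1.37, Kdr 1.53, Acta2 0.998, Abcc9 1.27, Pdgfrb 1.27 and Lyz2 0.94.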

Other observations

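Chosen only after the results were seen were the tests on mt-Nd6 and mt-Nd3, the endoplasmic reticulum test and the synthetase test. Most tested aminoacyl-tRNA synthetases of the cytosol, which load amino acids onto tRNAs, were higher in knockouts, also outside the members fixed in the stress response list. The synthetase list was written after its values were seen, and 5 of its tested members also belong to the stress response list. It was not tested against other genes. Of 18 tested, 13 were higher and 0 lower (edgeR adjusted p under 0.05), with a median log2 fold change of 1.79, and outside the stress response list 8 of 13 were higher. Lars rose 5.26-fold, Yars 4.94-fold, Iars 3.94-fold and Eprs 3.69-fold, from 10.5 to 38.7 CPM, while among those that did not pass were Kars (-0.24 ± 0.40 SE), Dars (0.53 ± 0.44 SE) and Rars (0.68 ± 0.46 SE). Of the genes for a mitochondrial enzyme alone, Iars2 (-0.24 ± 0.30 SE) and Vars2 (-0.19 ± 0.44 SE) could be tested, besides Lars2, left out as a dominant locus. The cytosolic median lay 1.999 above the mitochondrial one (log2), with Gars and Kars, which also encode the mitochondrial enzymes, counted as cytosolic. An exact permutation over these genes, which are not replicates, gave p = 0.0158 for the difference. With so few mitochondrial genes tested and a list chosen after its values were seen, a rise of both kinds alike cannot be told apart from a cytosolic one.

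mt-Nd6 fell less than the heavy-strand mRNAs. Carry-over of mtDNA was tested with the lowest heavy-strand mRNA density of each knockout library taken off mt-Nd6 there, and nothing in the controls. The log2 fold change of mt-Nd6 was then -1.79 ± 0.15 SE, above every heavy-strand mRNA. mt-Nd3 had the lowest density in every library, controls included. In knockouts it held 0.328, 0.264 and 0.552 counts per base, against 1.29, 1.13 and 1.94 for mt-Nd6. If the counts of mt-Nd3 run low for its length, the floor was too low. Carry-over as the whole cause is therefore not decided. Heavy-strand reads counted on the wrong strand would keep a fixed ratio to mt-Nd5 and mt-Cytb, and the log2 ratio instead rose by 3.70. This ratio restates the smaller fall of mt-Nd6. It goes only against such reads as the whole of the mt-Nd6 counts, and a part of them was not tested. The pooled light-strand tRNAs had a log2 fold change of -3.08 (95% Poisson interval -4.22 to -2.09), below mt-Nd6 at -1.36, which goes against a retention alike for all light-strand transcripts, and above the pooled heavy-strand tRNAs at -4.94 (-5.22 to -4.68), which goes against one of mt-Nd6 alone, but with 10 knockout counts and intervals of counting error only, neither is excluded. Of the pooled light-strand tRNA counts, 24 of 54 in controls and 6 of 10 in knockouts were those of mt-Tp, which lies nearer the promoter than mt-Nd6. A longer life of mt-Nd6 RNA than of other mtDNA mRNAs, or transcription that ends before the distal light-strand tRNAs, may contribute, and neither was tested. The second would not bear on the counts of mt-Tp.

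mt-Nd3 fell more than every other gene in the authors' deposited table. A larger loss of mt-Nd3 is argued against by the raw counts, where its log2 fold change was -4.92 ± 0.22 SE and within the range of the other heavy-strand mRNAs. The shift of the log2 ratio of normalised to raw values between groups was -2.79 beyond the median of those mRNAs. The authors' gene-specific normalisation is therefore a candidate explanation of its first rank, and why it treats mt-Nd3 apart stays open.

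The list of cytosolic ribosomal proteins passed camera upward, with 7 of 38 members past the edgeR test, and 10 sarcomere and calcium-handling transcripts fell relative to other nuclear transcripts, with the latter turning under no scaling. Fold changes fell with transcript length across nuclear genes (Spearman rho -0.26), and after a length trend was taken off the ribosomal protein median went from 0.73 to 0.45 (cameraPR p = 5.52e-04) and that of the 10 transcripts from -0.97 to -1.01. Length as the whole cause is thus argued against for the ribosomal list, although it may carry part of that shift. The 10 transcripts were picked for having fallen. Their median was likely to stay below 0 in any case, so the role of length is not decided for them. The endoplasmic reticulum list did not fall as those 10 did, with a median of -0.039 and a lower quartile of -0.16. All 24 tested sarcomere and calcium-handling genes had a median of only -0.13. The comparison with 10 picked transcripts therefore does not decide whether the knockout preparations held less endoplasmic reticulum. A different amount of cytosolic ribosomes bound to mitochondria, or a change in the heart muscle cells, stays open and was not tested.

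The 6 libraries make 10 splits into 3 and 3, the real one included, too few for a share under 0.05. The real split gave 451 genes, 17 mtDNA genes and 15 calls within the mtDNA, and the highest of the other splits gave 0, 0 and 0, so that 1 of 10 splits was as large for each. For gene lists the real split gave 11 and the highest other split 8, again 1 of 10. Every other split mixes knockouts into both groups, and the 8 lists called there show that camera at a preset correlation calls lists where edgeR called 0 single genes.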
